A study of Mus musculus with 25 samples.

How the data were processed

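Total RNA from the colon of female mice was measured on 25 single-colour Agilent arrays, each holding Cy3-labelled RNA of 1 mouse made from 100 ng of RNA with an integrity number over 7, per the labels' protocols. The arrays fall into 6 groups, wild type (WT) and Card9-/- before dextran sulfate sodium (DSS), at day 7 and at day 12, with 3 arrays in each day 0 group, 5 in the WT day 7 group, 4 in the Card9-/- day 7 group and 5 in each day 12 group. The design text names 5 mice for the Card9-/- day 7 group, and the other one is not analysed here. Replicate numbers come from the labels.

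Each array file holds spot intensity values on a linear scale that Agilent Feature Extraction 10.7.3.1 made from the scan, per the file headers and the submitters' processing notes. The processed intensity that the authors deposited is background-subtracted and corrected for trends across the array, with a stand-in value for spots not above background, per the file headers, and it is not normalized between arrays. Every array has 62976 spots, of which 59305 are not controls, for 55681 different probes. The deposited series value table holds 33418 of these probes on what the values show to be a log2 scale. Its columns correlated with the log2 median signal of the same arrays at 0.9954 or more and with the log2 processed signal at 0.9832 to 0.9915. Its sorted columns differed by at most 0.1012, the column medians lay between 7.906 and 7.911, and genes were not centred. How that table was normalized and how its probes were chosen is not given in the sources used here, so it served only as an alternative.

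The analysis used log2 of the processed intensity minus the 75th percentile of it on the same array. Control spots and spots with outlier flags were left out, saturated spots were kept, and spots of the same probe were averaged. A probe was kept where it was well above background on at least 3 of the 25 arrays, which left 36352 probes. A gene with several probes, of which there were 7344, was represented by the probe with the highest mean over all arrays, and 25496 genes or unnamed probes were tested. Several probes of a gene were called in opposite directions for 6 genes at day 7 against day 0 in the arrays labelled Card9-/- and for 1 gene at day 12 against day 7 in the same arrays. Of the probes, 27656 were named through their RefSeq accession and 3722 through a symbol or synonym in a gene table of the GRCm38.p6 assembly, and 24303 kept the name in the file. Probes of near-identical gene copies, such as the angiogenins and the Ugt2b family, cannot be told apart with certainty.

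Group means and their contrasts were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), in a single model of the 6 groups that share 1 estimate of the spread. A gene was called where its Benjamini-Hochberg adjusted p within the contrast was under 0.05. The contrasts were genotype at each day, day 7 and day 12 against day 0 and day 12 against day 7 within each genotype, and the difference between genotypes in the change over time. Differences are on the log2 scale with the standard error (SE) of the fit. Tables were handled with the R package data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9 in Python 3.11.15. Where a probe was not well above background on any array of a group, the fold is a bound, "at least N-fold". It sets the mean of the bright group against the mean, in the dim group, of the higher of the probe's own signal and the lowest signal of any probe well above background on that array.

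Genes were grouped in 45 gene lists of cell types, pathways and possible admixed tissues, and 839 of their 845 genes were on the array. Lists with at least 5 measured members were tested with camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a contrast. A camera result with an estimated correlation, fry, and an exact 2-sided permutation test of the list means stand beside it. The genes to name were Card9, the 10 largest rises and 10 largest falls of each contrast, the 4 members of a described list with the smallest p, and any member of the lists on the IL-22 and IL-17 axis, targets of the aryl hydrocarbon receptor (AhR) and antimicrobial defence. A rise or fall qualified with an adjusted p under 0.05, a proper gene symbol, a probe well above background on every array of at least 1 group of the contrast and, between 2 groups, no overlap of values. Of a list without called members, the 2 with the smallest p were taken. Groups, contrasts, lists, this rule and the alternatives were fixed before the data were examined, except 3 alternatives that leave out arrays or add a covariate and the list count without each array.

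The alternatives were normexp background correction with an offset of 50, quantile normalization, the series value table, no filter on dim probes, a filter of 13 arrays, every probe on its own, slide as a block, replicate number as a block, each contrast fitted on its own groups, and each array left out in turn. The 25 arrays lay on 4 slides, each of which held several groups, so the slide could be tested as a block, and each slide had a single scan. The fits were tested on simulated data made from 25496 genes of these arrays. Each gene was drawn on its own from a normal distribution with its own spread, the same in every group. The shares below therefore do not cover genes that vary together or arrays that stand apart. At a true log2 change of 1, the share of 100 changed genes recovered was 48% for genotype at day 0, 55% for genotype at day 7 and 47% for genotype at day 12, and at a change of 2 it was 56%, 69% and 69%. For day 7 against day 0 these shares were 45% and 67% in WT and 39% and 74% in the arrays labelled Card9-/-.

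On the arrays, the 75th percentile of the processed signal lay between 196.1 and 661.3 and between 48.0% and 67.9% of spots were well above background. The software marked at most 1 spot per array as saturated. For arrays, the number of mice per group limits the precision. Array coordinates are those of the mm9 build, as the files give them.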

Results

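Gene expression was measured in whole colon of female C57BL/6J mice aged 8 weeks, wild type (WT) or lacking Card9. CARD9 is the adaptor that links C-type lectin receptors for fungi to NF-κB signalling. Colitis was induced with 2% w/v DSS, a polymer that injures the colon epithelium when drunk, for 7 days, followed by 5 days of plain water. Colon was taken before DSS (day 0, 3 arrays per genotype), at the end of DSS (day 7, 5 WT and 4 Card9-/- arrays) and after the recovery (day 12, 5 arrays per genotype), 1 mouse per array. By its title the series concerns how CARD9 affects colitis through tryptophan metabolism of the gut microbiota and AhR, a receptor for tryptophan products. The comparisons below give the response to DSS and the recovery in each genotype, and the difference between genotypes at each day.

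The single Card9 probe, at chromosome 2, positions 26208462 to 26208521 (mm9), was brighter in the arrays labelled Card9-/-. Its log2 signal relative to the array's 75th percentile was -6.06 ± 0.47 (SD, n = 3) in WT and -1.20 ± 0.42 (n = 3) in Card9-/- at day 0. It was -5.43 ± 0.75 (n = 5) and -0.58 ± 0.10 (n = 4) at day 7, and -5.74 ± 1.6 (n = 5) and -0.94 ± 0.25 (n = 5) at day 12. The log2 differences were 4.86 ± 0.67 (SE), 4.85 ± 0.55 and 4.81 ± 0.52, with limma adjusted p = 0.01, 0.000454 and 0.000199. At day 0, where the probe was not well above background on any WT array, the difference was at least 11.4-fold. At days 7 and 12 it was well above background on 1 of 5 WT arrays each, so the sizes of those differences are uncertain too. With normexp background correction the differences were 2.10, 2.28 and 2.12. The lowest array labelled Card9-/- (-1.52) lay 1.41 above the highest labelled WT (-2.93), so 0 of the 25 arrays lay on the other side. This direction is opposite to loss of a transcript. Which part of the gene was removed is not given in the sources used here, and a probe outside the removed part cannot check its loss. Such a probe would not by itself make the signal higher in the arrays labelled Card9-/-. Genotype names below are therefore the labels of the arrays, and each direction between genotypes rests on those labels.

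**Figure D1:**
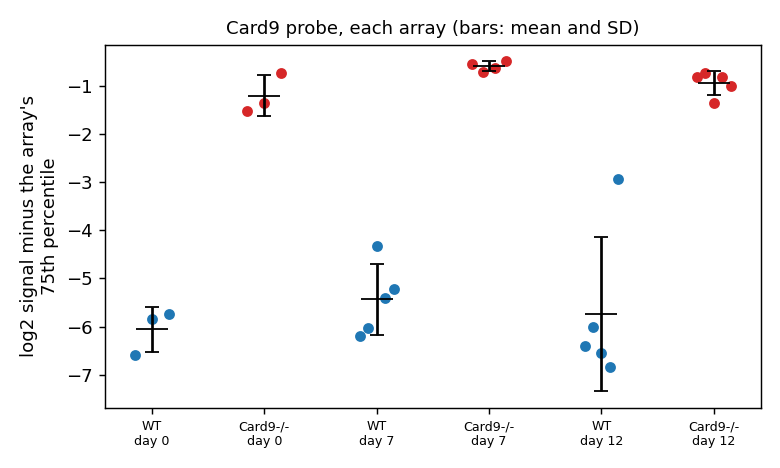
Log2 signal of the Card9 probe minus each array's 75th percentile of signal, for each array of the 6 groups, with bars for the mean and SD. All arrays labelled Card9-/- lie at -1.52 or above and all labelled WT at -2.93 or below.

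The first comparison asked what 7 days of DSS did to the colon of WT mice. Genes of neutrophils, inflammatory cytokines, acute phase proteins, matrix-degrading enzymes and antimicrobial lectins rose, while angiogenin and intelectin genes fell. The largest rises were in Reg3b and Reg3g, lectins that epithelial cells release against bacteria (log2 change 7.92 ± 1.58 (SE), 242-fold, and 6.85 ± 1.36, 116-fold), and in S100a9 and S100a8, the subunits of the neutrophil protein calprotectin (7.87 ± 0.80, 234-fold, and at least 67-fold). Next came the matrix metalloproteinases Mmp3, Mmp10 and Mmp13 (6.25 ± 0.89, 5.65 ± 1.00 and 5.60 ± 1.04), the cytokines Il1b and Il11 (6.05 ± 0.81 and 5.74 ± 0.95) and the lectin receptor Clec4d (at least 14-fold). The largest falls included those of Ang4, an antimicrobial ribonuclease (-6.46 ± 0.59), Ang2 (-6.14 ± 0.49) and Ang (-4.81 ± 0.36), and of Itln1, a lectin that binds microbial sugars (-6.09 ± 0.59). The muscarinic receptor gene Chrm3 fell by at least 7.63-fold and Pla2g4c by 3.36 ± 0.77. The largest adjusted p among these genes was 0.0147, for Pla2g4c. In all, 1102 genes were called, 512 up and 590 down.

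By gene list in WT at day 7, 16 of 23 inflammatory cytokine and chemokine genes rose and none fell, 20 when adjusted over the list alone (mean log2 change 3.36 ± 0.54, adjusted p = 2.32e-24). Cxcl1, a chemokine that attracts neutrophils, rose at least 19.7-fold and Ccl3 at least 12.6-fold. Of the complement and acute phase list 14 of 17 rose (16 adjusted over the list alone), among them Lrg1 (4.87 ± 0.43) and Lbp (4.01 ± 0.57). Of 22 neutrophil genes 9 rose (14 adjusted over the list alone). Of 9 mast cell genes 5 rose and 1, Kit, fell (7 and 1 adjusted over the list alone), with the protease Mcpt4 up by 1.90 ± 0.35. Of 19 cholesterol synthesis genes 10 fell (14 adjusted over the list alone), including Hmgcs1 (-1.06 ± 0.19), Sqle (-0.92 ± 0.15) and Cyp51 (-0.90 ± 0.13). The list mean was -0.57 ± 0.10. These 5 lists were also called with an estimated correlation (adjusted p = 0.0367 for 4 of them and 0.0459 for neutrophil). Of 26 antimicrobial defence genes 10 rose and 2 fell (11 and 2 adjusted over the list alone), with Lcn2, a protein that withholds iron from bacteria, up by 3.46 ± 0.58, Saa3 by 4.92 ± 0.84, Slpi by 3.44 ± 0.50 and Fut2 by 1.33 ± 0.20. Of 14 tuft cell genes 7 fell (9 adjusted over the list alone), among them Bmx (-1.22 ± 0.17) and Sh2d6 (-1.30 ± 0.26). Of 11 matrix proteases 5 rose (10 adjusted over the list alone). Adjusted p = 0.0658 with an estimated correlation for each of these 3 lists.

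Further lists in WT at day 7 were called with the preset but not with an estimated correlation. Of 34 interferon response genes 9 rose (21 adjusted over the list alone), including the guanosine triphosphatase gene Ifi47 (2.08 ± 0.43), Ifit2 (2.70 ± 0.61) and the immunoproteasome subunit Psmb8 (1.84 ± 0.39). This list gave adjusted p = 4.64e-14 and adjusted p = 0.229 with an estimated correlation. Of 19 goblet cell genes 5 fell (5 adjusted over the list alone), among them the mucus protein gene Fcgbp (-1.38 ± 0.27), Tpsg1 (-1.12 ± 0.15) and Ern2 (-0.79 ± 0.14). For goblet cells the test gave adjusted p = 2.4e-06 and adjusted p = 0.193 with an estimated correlation. Of 23 macrophage genes 6 rose (12 adjusted over the list alone), of 27 extracellular matrix and fibroblast genes 6 (13 adjusted over the list alone) and of 18 endothelium genes 1 (5 adjusted over the list alone). These lists had adjusted p = 0.219, 0.348 and 0.378 with an estimated correlation. Socs3, a feedback inhibitor of cytokine signalling, rose by 3.34 ± 0.45 and Stat3 by 0.98 ± 0.18, the called members of the IL-22 and IL-17 axis, whose list was not called (adjusted p = 0.0641). Il22 itself was not called (adjusted p = 0.0788). Ido1, which starts tryptophan breakdown in the kynurenine pathway, rose by 5.24 ± 0.80 (37.8-fold, adjusted p = 0.000711), while the tryptophan metabolism list (adjusted p = 0.933) and the AhR targets (0 of 9 called, 1 adjusted over the list alone, adjusted p = 0.993) were not called. The AhR target Cyp1a1 had a log2 difference of 1.96 ± 0.59 with adjusted p = 0.0649. The AhR target mean was 0.89 in WT day 7 replicate 1, whose mean of proximal colon genes was 2.30, and -0.13 to 0.08 in the others of its group. Leaving out WT day 0 replicate 1, 2 or 3 took the count from 1102 to 393, 400 or 563, and a fit on these groups alone to 38.

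In the arrays labelled Card9-/-, genes of neutrophils, macrophages and matrix proteases were higher after 7 days of DSS, and glucuronosyltransferase genes were lower. S100a9 rose at least 2060-fold, S100a8 at least 581-fold, Il1b at least 273-fold, and the matrix metalloproteinases Mmp3 and Mmp10 at least 205- and 169-fold. The neutrophil chemokine Cxcl5 rose at least 123-fold, Acod1, which makes itaconate in macrophages, at least 142-fold, the neutrophil gene Retnlg at least 89.5-fold and Clec4d at least 60.3-fold, each from a day 0 level that was not well above background. The largest adjusted p among these genes was 2.83e-05, for Acod1. The largest falls included those of the glucuronosyltransferase genes Ugt2b5 (-6.36 ± 1.31), Ugt2b37 (at least 27.1-fold) and Ugt2b36 (-5.12 ± 1.01). Also among them were Slc51a, a bile acid transporter subunit (-5.10 ± 1.62, adjusted p = 0.0301), Cyp4b1 (-4.95 ± 1.31) and Ang4 (-4.73 ± 0.61). Lrat, whose enzyme esterifies retinol, fell at least 10.5-fold and the urea cycle gene Otc by 4.54 ± 0.76. In all, 4998 genes were called, 1760 up and 3238 down. The mean of 7 Hox genes that mark proximal colon was 2.51 and 2.20 above the WT day 0 mean in Card9-/- day 0 replicates 1 and 2, -0.10 in replicate 3, and between -0.36 and 0.22 in the Card9-/- day 7 arrays. With that mean as a covariate, a setting chosen after the data were seen, 3263 genes were called. The falls of Slc51a (-1.31, adjusted p = 0.369) and Cyp4b1 (-1.76, adjusted p = 0.0578) were then no longer called. Colon position and DSS are thus not separated for such falls. For the glucuronosyltransferase gene Ugt2b5 the same limit appeared at day 12, as given below. Leaving out Card9-/- day 0 replicate 1 or 2 gave 3224 or 3302 called genes, and a fit on these groups alone 2396.

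The gene lists in the arrays labelled Card9-/- at day 7 are given with the count adjusted over the list alone in square brackets. Of the inflammatory cytokines and chemokines 21 of 23 rose [21], of neutrophil genes 17 of 22 [19], of complement and acute phase genes 16 of 17 [16], of macrophage genes 19 of 23, with 2 down [19 and 2], of antimicrobial defence genes 17 of 26, with 2 down [19 and 2], of matrix proteases 10 of 11 [10] and of mast cell genes 7 of 9, with 1 down [8 and 1]. With an estimated correlation these 7 lists had adjusted p between 0.00984 and 0.0423. The macrophage gene Chil3 rose at least 71.1-fold, the complement gene C1qb by 2.46 ± 0.31 and Cd68 by 2.98 ± 0.39. Among the antimicrobial genes, Slpi rose by 5.31 ± 0.53, Lcn2 by 5.18 ± 0.60, Nos2 by 4.41 ± 0.63, Reg3g by 4.88 ± 1.42 and the epithelial oxidase Duox2 by 1.76 ± 0.38, while Ang4 and Itln1 (-4.18 ± 0.62) fell.

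Other lists at day 7 in these arrays were called with the preset but not with an estimated correlation. Of 10 MHC class II genes 9 rose [9 adjusted over the list alone], with H2-Aa up by 2.76 ± 0.44 and Cd74 by 2.80 ± 0.48 (adjusted p = 0.0918 with an estimated correlation). The MHC class II mean was 0.70 to 1.46 in these day 7 arrays and -2.26, -1.77 and 0.41 in Card9-/- day 0 replicates 1 to 3. Of 27 extracellular matrix and fibroblast genes 23 rose [23] (adjusted p = 0.106 with an estimated correlation). Of 34 interferon response genes 19 rose [24], including Nlrc5 (3.33 ± 0.64) and Cxcl10 (4.54 ± 0.94) (adjusted p = 0.156 with an estimated correlation). Of 33 xenobiotic metabolism genes 21 fell [23], among them the sulfotransferases Sult1a1 (-2.44 ± 0.28) and Sult1d1 (-1.84 ± 0.27) and the glutathione transferase Gstm3 (-2.27 ± 0.28) (adjusted p = 0.14 with an estimated correlation). The xenobiotic metabolism mean was 0.85 and 0.80 in Card9-/- day 0 replicates 1 and 2 and 0.26 in replicate 3, and with the proximal colon covariate the fall was -0.93. Of 26 oxidative phosphorylation genes 18 fell [23], by a list mean of -0.45 ± 0.09, with Ndufs1 at -0.58 ± 0.09 and Sdha at -0.54 ± 0.10 (adjusted p = 0.198 with an estimated correlation). Of 14 tuft cell genes 10 fell [10] (adjusted p = 0.198 with an estimated correlation). Of 19 goblet cell genes 7 fell [8], including Muc2, the main mucin of the colon (-0.88 ± 0.20), and the secretory lineage factor Atoh1 (-1.39 ± 0.21) (adjusted p = 0.365 with an estimated correlation). Dclk1, a tuft cell marker, fell by 1.71 ± 0.40 but had a difference of 0.55 with normexp and 0.49 in the series value table. Of the IL-22 and IL-17 axis 4 of 12 rose and 1 fell [5 and 1], namely Socs3 (3.91 ± 0.47), Stat3 (0.80 ± 0.19), Il17a (at least 2.34-fold) and the chemokine receptor Ccr6 (3.49 ± 0.93), against the receptor Il22ra1 (-0.61 ± 0.18). The axis had adjusted p = 0.0179 and adjusted p = 0.252 with an estimated correlation. Il22 was not called (adjusted p = 0.0535). The AhR targets were not called as a list (adjusted p = 0.615), with Nqo1 (-2.02 ± 0.38) and Ugt1a6b (-1.42 ± 0.32) down and Cyp1b1 up at least 1.5-fold [1 up and 3 down], while Cyp1a1 was -0.32 ± 0.62 with adjusted p = 0.801. In tryptophan metabolism, Kmo (2.42 ± 0.37) and Il4i1 (1.98 ± 0.51) rose and Ddc (-0.81 ± 0.24) and Maoa (-0.69 ± 0.18) fell, with the list not called (adjusted p = 0.0936).

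Markers of other tissues moved with this group. All 5 red blood cell genes rose at day 7 in the arrays labelled Card9-/- [5 adjusted over the list alone], with Hba-a1 up by 3.83 ± 0.82 (adjusted p = 0.0545 with an estimated correlation). Pancreatic acinar genes, which encode digestive enzymes, averaged 14.39 and 14.78 above the WT day 0 mean in replicates 2 and 3 and -0.64 and 0.10 in replicates 1 and 4. They averaged 13.93 in Card9-/- day 12 replicate 1 and 8.51 in WT day 12 replicate 5. Without these 4 arrays, a setting chosen after the data were seen, 3274 genes were called at day 7 against day 0 in the arrays labelled Card9-/-. At day 0, 7 of the 11 acinar genes were not well above background on any array of either genotype, so the sizes of the acinar means are uncertain. With bounds for dim genes, the median acinar change at day 7 in the arrays labelled Card9-/- was 6.38 instead of 7.89.

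**Figure D2:**
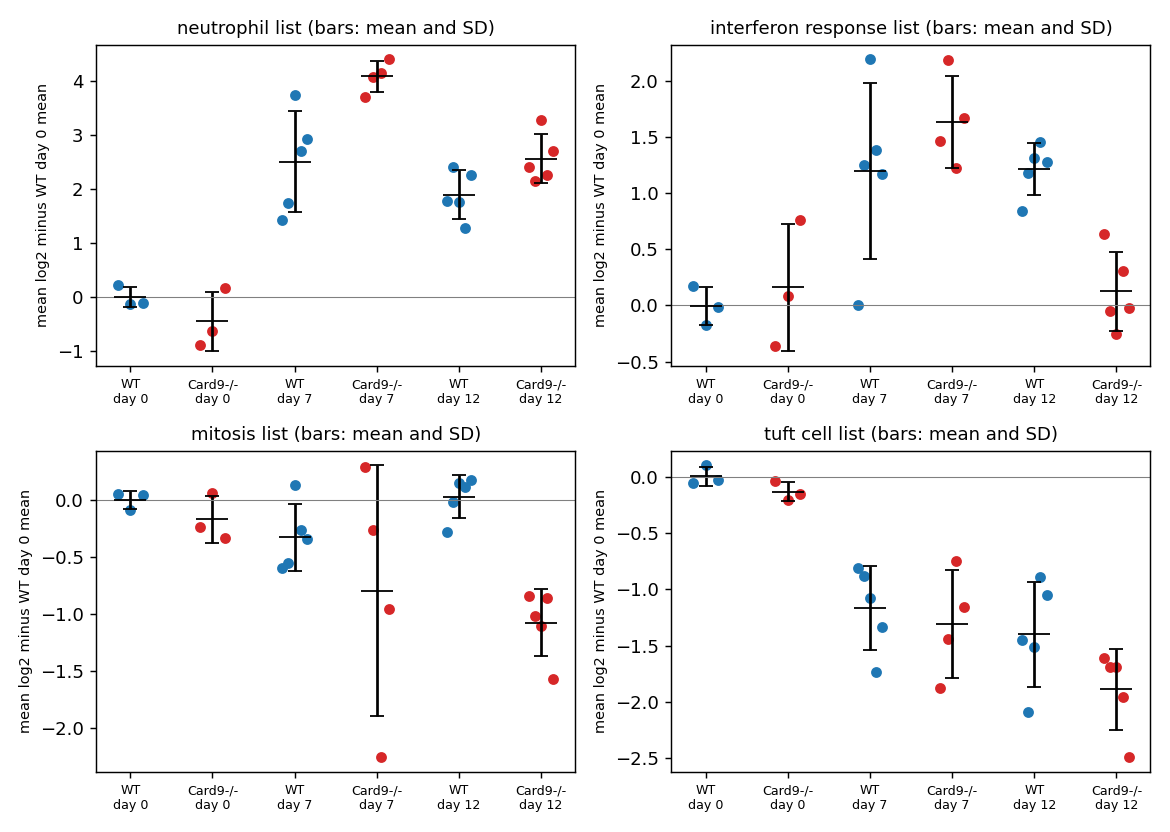
Mean log2 signal of the neutrophil, interferon response, mitosis and tuft cell lists in each array, relative to the WT day 0 mean, with bars for the mean and SD of each group. The interferon response means of the Card9-/- day 12 arrays lie between -0.25 and 0.64 and those of the WT day 12 arrays between 0.84 and 1.45, and the tuft cell means lie below 0 in every array at days 7 and 12.

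The genotypes shared much of the response to DSS. Of the 512 genes that rose in WT and the 1760 that rose in the arrays labelled Card9-/-, 407 rose in both, against 35.3 for independent lists, and of the 590 and 3238 that fell, 376 fell in both, against 74.9. Across genes, which are not independent replicates, the log2 changes of the genotypes correlated at r = 0.558. The test of the difference between genotypes in the change from day 0 to day 7 called 1 gene with limma, against 2947 at an unadjusted p under 0.05. That gene was Slc16a6, a member of the monocarboxylate transporter family, which rose more in the arrays labelled Card9-/- (1.17 ± 0.18, adjusted p = 0.039) and was not called with normexp (adjusted p = 0.16), with no filter on dim probes (adjusted p = 0.111) or with the proximal colon covariate (adjusted p = 0.326). For Cyp1a1 this difference was -2.29 ± 0.86 (adjusted p = 0.297) and for Nqo1 -1.21 ± 0.53 (adjusted p = 0.382), and Il22 was not called (adjusted p = 0.973). The neutrophil list had the smallest adjusted p in this test, with 0 of 22 members called [10 adjusted over the list alone], a mean of 2.02 ± 0.60, adjusted p = 1.03e-14 and adjusted p = 0.0587 with an estimated correlation.

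The next comparison followed recovery from day 7 to day 12. In WT mice acute phase genes fell and mast cell protease genes rose. Lbp, which binds bacterial lipopolysaccharide, fell by 3.38 ± 0.49 (adjusted p = 0.00672), and the chemokine Ccl17 by 1.44 ± 0.31. Mcpt1 and Mcpt4, proteases of mast cells, rose by 2.07 ± 0.40 and 1.67 ± 0.30, the lactate transporter Slc16a3 by 1.63 ± 0.26, the chloride channel regulator Clca4a by 1.40 ± 0.28 and the cornified envelope gene Lce3b by 3.69 ± 0.64. Genes of the circadian clock moved in both directions, with Dbp (-2.95 ± 0.45) and Tef (-1.78 ± 0.30) down and Arntl (1.31 ± 0.22) and Cry1 (1.38 ± 0.30) up, and the transcription factor Zbtb16 was down by 2.81 ± 0.37. In all, 124 genes were called, 93 up and 31 down. Of 17 complement and acute phase genes 2 fell (13 adjusted over the list alone). The list had adjusted p = 4.67e-14 and adjusted p = 0.226 with an estimated correlation. Of 19 cholesterol synthesis genes 0 rose (9 adjusted over the list alone). The list mean was 0.30 ± 0.08, with adjusted p = 1.71e-07 and adjusted p = 0.401 with an estimated correlation. Of 9 mast cell genes 2 rose (5 adjusted over the list alone). The list had adjusted p = 0.00588 and adjusted p = 0.401 with an estimated correlation. The count of 124 moved to 28, 75, 36, 33 and 75 without WT day 12 replicates 1 to 5, and to 227 and 74 without WT day 7 replicates 1 and 3. With limma on these groups alone 0 genes were called, against 2575 at an unadjusted p under 0.05.

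In the arrays labelled Card9-/-, day 12 against day 7 brought a fall of interferon response genes and of chemokines and a rise of goblet cell genes. The interferon-induced chemokines Cxcl9 and Cxcl10 fell by 3.68 ± 0.91 and 3.34 ± 0.82, Ccl3 and Ccl4 by 3.23 ± 0.68 and 3.33 ± 0.68, Acod1 by 3.40 ± 0.91, Chil3 by 3.39 ± 0.79 and Lbp by 3.24 ± 0.52. Mmp3 fell by 3.04 ± 0.81 and the methyltransferase gene Bhmt by 3.89 ± 0.92. Rises were smaller, led by Reg4, a lectin of secretory epithelial cells (2.76 ± 0.59), the potassium channel subunit Kcne2 (2.44 ± 0.44), the goblet-related gene Agr3 (at least 2.19-fold), Fzd9 (2.19 ± 0.45) and the epithelial transcription factor Grhl3 (2.12 ± 0.41). In all, 1960 genes were called, 1458 up and 502 down. Of 34 interferon response genes 26 fell (32 adjusted over the list alone), with Ifit3 at -1.56 ± 0.26, Mx2 at -1.78 ± 0.31 and Zbp1 at -1.88 ± 0.33 (list adjusted p = 1.52e-27 and adjusted p = 0.133 with an estimated correlation). Of 23 inflammatory cytokine and chemokine genes 6 fell (13 adjusted over the list alone), with adjusted p = 0.178 with an estimated correlation. Of 23 macrophage genes 3 fell (9 down and 1 up adjusted over the list alone), with adjusted p = 0.258 with an estimated correlation. Of 26 antimicrobial genes 4 fell (6 adjusted over the list alone), namely Ltf (-2.63 ± 0.50), Lcn2 (-2.60 ± 0.53), Saa3 (-2.86 ± 0.77) and Nos2 (-1.90 ± 0.55) (adjusted p = 0.133 with an estimated correlation). Of 19 cholesterol synthesis genes 7 rose (12 adjusted over the list alone) (adjusted p = 0.147 with an estimated correlation). Of 19 goblet cell genes 7 rose (9 adjusted over the list alone), among them Ern2 (0.96 ± 0.13), Tpsg1 (0.89 ± 0.14) and Atoh1 (0.92 ± 0.18) (adjusted p = 0.357 with an estimated correlation). Nqo1 rose by 1.43 ± 0.34 and Il22ra1 by 0.55 ± 0.15, while the lists of AhR targets and of the IL-22 and IL-17 axis were not called (adjusted p = 0.767 for each). Ido1 fell by 2.68 ± 0.73. Slc4a1, an anion exchanger of red blood cells, fell by 2.55 ± 0.58. Without the 4 arrays that carried pancreatic transcripts 247 genes were called. Without Card9-/- day 7 replicates 2 or 4 and Card9-/- day 12 replicates 2 or 5 the counts were 1033, 1198, 1160 and 1204, and in a fit on these groups alone 683.

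Between day 7 and day 12, 48 genes rose in both genotypes of 93 and 1458, against 5.32 for independent lists, and 12 fell in both of 31 and 502, against 0.61. The test of the difference between genotypes in this change called 2 genes with limma, both lower in the arrays labelled Card9-/- and both induced by interferon, against 1965 at an unadjusted p under 0.05. Ifit1 had a difference of -2.26 ± 0.34 and Oasl1 of -1.29 ± 0.19 (adjusted p = 0.0203 for each). Ifit1 was 0.01 and 0.45 at day 7 and 0.80 and -1.02 at day 12 in WT and Card9-/-. Neither gene was called with normexp background, with quantile normalization or without the 4 arrays that carried pancreatic transcripts. Of the 34 interferon response genes 1 was called lower in this test (23 adjusted over the list alone). The list mean was -1.52 ± 0.44, with adjusted p = 8.64e-34 and adjusted p = 0.0988 with an estimated correlation.

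Day 12 was also set against day 0, to ask what remained after recovery. In WT mice calprotectin, Reg3 and mast cell genes were still raised and angiogenin and tuft cell genes still lowered. S100a9 was up by 7.43 ± 0.80 (172-fold), S100a8 at least 52-fold, Reg3b by 6.81 ± 1.58, Reg3g by 5.86 ± 1.36, Il1b by 5.75 ± 0.81, Il11 by 4.91 ± 0.95, Cxcl5 by 4.71 ± 0.59, Prss22 at least 6.92-fold and Clec4e, a lectin receptor that signals through CARD9, at least 6.39-fold. Mptx1, a pentraxin of the intestinal epithelium, fell by 8.07 ± 1.60 (268-fold, adjusted p = 0.0108). Itln1 fell by 5.32 ± 0.59, Ang4 by 5.01 ± 0.59 and Ang2 by 5.01 ± 0.49. In all, 441 genes were called, 288 up and 153 down. Of 9 mast cell genes 6 rose (6 adjusted over the list alone), with Mcpt1, Mcpt2 and Mcpt4 up by 3.76 ± 0.46, 3.82 ± 0.50 and 3.56 ± 0.35 (adjusted p = 0.00505 with an estimated correlation). Of 14 tuft cell genes 7 fell (11 adjusted over the list alone), with Bmx at -1.30 ± 0.17 and Sh2d6 at -1.35 ± 0.26 (adjusted p = 0.0278 with an estimated correlation). Of 34 interferon response genes 4 rose (28 adjusted over the list alone), among them Ifit1 (1.43 ± 0.27), Mx2 (1.68 ± 0.33) and Ifit2 (3.04 ± 0.61). The interferon list had adjusted p = 2.43e-17 and adjusted p = 0.18 with an estimated correlation. Socs3 (2.52 ± 0.45), Stat3 (0.70 ± 0.18) and Ido1 (4.58 ± 0.80) were raised. Without WT day 0 replicates 1, 2 and 3 the count was 112, 141 and 234. Without WT day 12 replicates 2 and 5 it was 231 and 250.

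In the arrays labelled Card9-/-, day 12 against day 0 gave 1769 called genes, 943 up and 826 down, with neutrophil, macrophage and mast cell genes raised and tuft cell, glucuronosyltransferase and angiogenin genes lowered. S100a9 rose at least 396-fold, S100a8 at least 112-fold, Il1b at least 68.5-fold, Cxcl5 at least 54.5-fold, Mmp10 at least 33.5-fold, Mmp3 at least 24.9-fold and Clec4d at least 14.2-fold, and the interleukin-33 receptor gene Il1rl1 by 6.24 ± 0.83 and Il11 by 6.18 ± 0.95. Ugt2b5 fell by 6.24 ± 1.25, Slc51a by 5.75 ± 1.55, Ugt2b37 by 5.65 ± 1.12, Ang4 by 5.22 ± 0.59 and Cyp4b1 by 4.59 ± 1.25. Of the mast cell list 7 of 9 rose and 1 fell (7 and 1 adjusted over the list alone), with Mcpt4 up by 4.68 ± 0.35, Mcpt1 by 4.73 ± 0.46 and Cpa3 at least 6.91-fold (adjusted p = 0.00075 with an estimated correlation). Of neutrophil genes 13 of 22 rose (16 adjusted over the list alone), of macrophage genes 15 of 23 (18, with 1 down, adjusted over the list alone), and of tuft cell genes 10 of 14 fell (11 adjusted over the list alone). These lists had adjusted p = 0.0219, 0.0309 and 0.0247 with an estimated correlation. Of 9 plasma cell genes 3 rose (5 adjusted over the list alone), Mzb1, Tnfrsf13b and Pou2af1, by 2.24 ± 0.58, 2.28 ± 0.59 and 2.56 ± 0.68 (adjusted p = 0.000329 and adjusted p = 0.0868 with an estimated correlation). Relative to WT day 0, the plasma cell mean was -2.10, -1.35 and -0.25 in Card9-/- day 0 replicates 1 to 3. It was -0.38 to 0.32 in the Card9-/- day 12 arrays, so the rise rests largely on low day 0 values. Ifit1 (-1.27 ± 0.27) and Irf7 (-0.87 ± 0.21) fell, and the interferon response list was not called (adjusted p = 0.44). Socs3 (2.83 ± 0.45), Stat3 (0.68 ± 0.18) and Ccr6 (3.92 ± 0.89) rose, with the IL-22 and IL-17 axis called (3 of 12 up, 3 adjusted over the list alone, adjusted p = 0.00225 and adjusted p = 0.133 with an estimated correlation). The proximal colon list, raised in Card9-/- day 0 replicates 1 and 2, was lower at day 12 by -1.96 ± 0.60 (adjusted p = 0.000914 and adjusted p = 0.095 with an estimated correlation). With it as a covariate 239 genes were called and Ugt2b5 (-2.81, adjusted p = 0.179), Slc51a (-1.06, adjusted p = 0.6) and Cyp4b1 (-0.64, adjusted p = 0.64) were not. Without Card9-/- day 0 replicates 1 and 2 the count was 524 and 479. Without Card9-/- day 12 replicates 3 and 5 it was 1123 and 1144. Both genotypes shared 157 of the 288 and 943 raised genes and 83 of the 153 and 826 lowered genes.

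Between genotypes before DSS, limma called 1 gene, Card9 itself, with 1268 genes at an unadjusted p under 0.05. With slide as a block Card9 was not called (4.64, adjusted p = 0.131), and the 1 gene called in its place was lower in the arrays labelled Card9-/-. In the series value table the 1 called gene was lower as well. At day 0 only slide 4 held arrays of both genotypes, so genotype and slide were partly confounded there. Of the 45 lists 22 were called with the preset correlation, 9 up and 13 down, and 0 with an estimated correlation. Among them were DNA replication (-0.39 ± 0.28), fatty acid oxidation and PPAR (0.60 ± 0.28) and xenobiotic metabolism (0.64 ± 0.28), without called members (2 of fatty acid oxidation adjusted over the list alone). In Card9-/- day 0 replicates 1 to 3 the fatty acid oxidation mean was 1.13, 0.71 and -0.04, and the xenobiotic metabolism mean 0.85, 0.80 and 0.26. Of 11 small intestine genes 0 were called (4 adjusted over the list alone). The mean difference was 1.61 ± 0.50, with adjusted p = 6.58e-07 and adjusted p = 0.158 with an estimated correlation. The bile acid transporter Slc10a2 was not called (3.98 ± 1.10, adjusted p = 0.638), and the brush border enzyme Sis was not called either (adjusted p = 0.79). Of 10 MHC class II genes 0 were called (5 lower adjusted over the list alone), with H2-Aa at -1.75 ± 0.47 (adjusted p = 0.635), a list mean of -1.21 ± 0.53, adjusted p = 2.88e-10 and adjusted p = 0.241 with an estimated correlation. The MHC class II mean was -2.26 and -1.77 in Card9-/- day 0 replicates 1 and 2 and 0.41 in replicate 3. The Hox genes of proximal colon were 1.54 ± 0.67 higher (adjusted p = 0.00468 and adjusted p = 0.383 with an estimated correlation), in replicates 1 and 2 alone. The small intestine mean was 2.47 and 1.74 in those replicates against 0.62 in the third. Neither the AhR targets (adjusted p = 0.0991, Cyp1a1 1.86 ± 0.66 with adjusted p = 0.789) nor the IL-22 and IL-17 axis (adjusted p = 0.926, Il22 with adjusted p = 1) were called. With 3 arrays per group an exact permutation test of a list cannot go below p = 0.1. The count of called genes was 58 without Card9-/- day 0 replicate 3, 5 without Card9-/- day 0 replicate 1, and 0 without Card9-/- day 0 replicate 2 or any WT day 0 array.

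**Figure D3:**
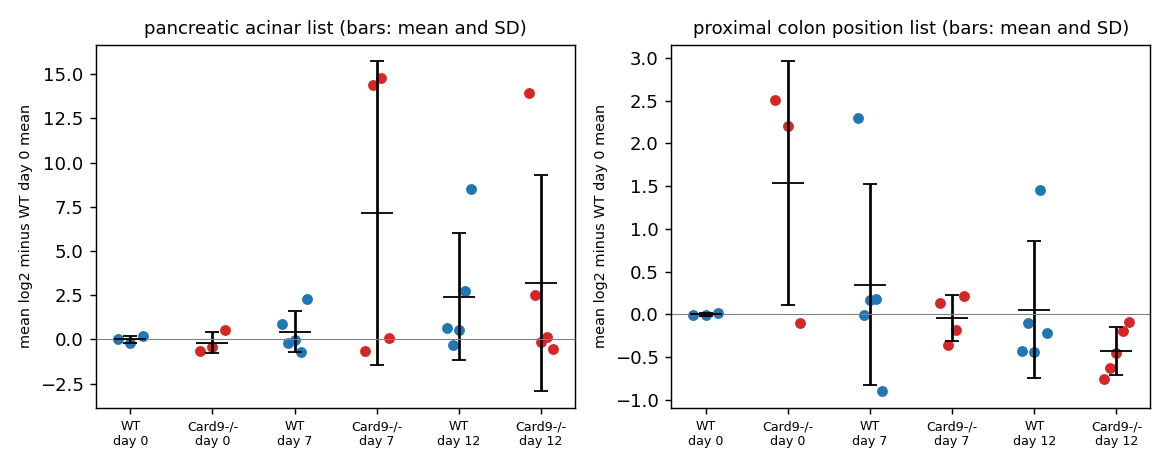
Mean log2 signal of the pancreatic acinar and proximal colon position lists in each array, relative to the WT day 0 mean, with bars for the mean and SD of each group. The acinar list reaches 14.39, 14.78, 13.93 and 8.51 in 4 arrays, and the proximal list 2.51 and 2.20 in Card9-/- day 0 replicates 1 and 2, 2.30 in WT day 7 replicate 1 and 1.46 in WT day 12 replicate 4.

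At the end of DSS, 140 genes were called between genotypes, 37 higher, Card9 among them, and 103 lower in the arrays labelled Card9-/-. Without the arrays that carried pancreatic transcripts 1 gene was called, and in a fit on these groups alone also 1, each higher. Chance is not excluded for the count of 140, with 11 of 100 splits of the arrays as large. Of the lists, red blood cells held 2 of the higher genes and CARD9 signalling, neutrophils and eosinophils 1 each. Higher were Slc4a1 (at least 5.21-fold, adjusted p = 0.0398) and the hemoglobin chaperone Ahsp (1.96 ± 0.41), the interleukin-5 receptor Il5ra of eosinophils (2.26 ± 0.47), the neutrophil protease inhibitor Stfa2l1 (2.00 ± 0.40), the lubricating proteoglycan Prg4 (2.69 ± 0.59), Nfasc (1.63 ± 0.30), Asprv1 (1.27 ± 0.28) and the T cell co-stimulator Tnfrsf4 (1.18 ± 0.19). Lower were the phospholipase Pla2g3 (-1.60 ± 0.34), Klhl24 (-1.23 ± 0.22), Pyroxd2 (-1.12 ± 0.25), the carotenoid-cleaving enzyme Bco2 (-0.99 ± 0.18), the secretory transcription factor Creb3l4 (-0.96 ± 0.14, adjusted p = 0.00834), Slc12a8 (-0.90 ± 0.16), the deacetylase Hdac11 (-0.87 ± 0.19) and Sult1a1 (-1.08 ± 0.24). Calprotectin genes had differences of 3.18 ± 0.76 (S100a8, adjusted p = 0.059) and 3.06 ± 0.74 (S100a9, adjusted p = 0.0592), and Lcn2 of 1.81 ± 0.53 (adjusted p = 0.1). Reg3g (0.27 ± 1.25, adjusted p = 0.954), Il22 (0.02 ± 0.81) and Cyp1a1 (-0.43 ± 0.55, adjusted p = 0.766) were not called.

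At day 7, 26 of the 45 lists were called between genotypes with the preset correlation, 23 up and 3 down, and 0 with an estimated correlation. Of 22 neutrophil genes 1 was higher in the arrays labelled Card9-/- (16 adjusted over the list alone). The mean difference was 1.57 ± 0.38, with adjusted p = 8.74e-15 and adjusted p = 0.0577 with an estimated correlation. Within slides 1 to 4 this difference was 1.33, 2.29, 1.22 and 1.69. Of 26 antimicrobial genes 0 were called (5 higher adjusted over the list alone). Their mean difference was 1.35 ± 0.37, with an exact permutation p = 0.00794, which does not pass over the 45 lists (adjusted p = 0.143), and adjusted p = 0.0577 with an estimated correlation. The antimicrobial defence means were 2.32, 4.10, 3.78 and 2.79 in Card9-/- day 7 replicates 1 to 4, of which 2 and 3 carried pancreatic transcripts, and without those arrays the difference was 0.65. Of 5 red blood cell genes 2 were higher (5 adjusted over the list alone). The mean difference was 2.97 ± 0.61 and adjusted p = 0.0577 with an estimated correlation, and within slides the difference of the red blood cell list was 2.23, 1.87, 5.05 and 3.11. The pancreatic acinar list differed by 6.72 ± 3.19 (0 called, 0 adjusted over the list alone, adjusted p = 4.09e-07 and adjusted p = 0.268 with an estimated correlation). The IL-22 and IL-17 axis (0.29 ± 0.23, adjusted p = 0.197) and the AhR targets (-0.01 ± 0.19, adjusted p = 0.728) were not called. The tryptophan metabolism list was higher by 0.38 ± 0.21 with 0 of 17 called, also 0 adjusted over the list alone (adjusted p = 0.0066 and adjusted p = 0.266 with an estimated correlation). Its means in Card9-/- day 7 replicates 1 to 4 were 0.10, 0.79, 1.20 and 0.47, highest in the replicates with pancreatic transcripts, and without the arrays that carried them the difference was 0.03 and not called (adjusted p = 0.446). Of the called genes 26.4% were higher, against 41.5% with normexp and 40.9% in the series value table. The count of 140 was 1 without the arrays that carried pancreatic transcripts, 1 in a fit on these groups alone, 357 with slide as a block, and 15, 4, 2266, 6 and 49 without WT day 7 replicates 1 to 5 and 653, 12, 4 and 41 without Card9-/- day 7 replicates 1 to 4.

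At day 12, 18 genes differed between genotypes, 5 higher and 13 lower in the arrays labelled Card9-/-. Apart from Card9, the higher genes were 4 circadian clock genes, and 2 of the lower genes belong to the interferon response list. Higher were Dbp (3.19 ± 0.45, 9.13-fold, adjusted p = 0.00346), Ciart (2.69 ± 0.44), Tef (1.97 ± 0.30) and Nr1d2 (1.10 ± 0.18). Lower were the antiviral genes Mx2 (-2.03 ± 0.29), Ifit1 (-1.82 ± 0.23, adjusted p = 0.00187), Oas3 (-1.61 ± 0.28), Cmpk2 (-1.17 ± 0.19) and Oasl1 (-0.87 ± 0.13), the apolipoprotein L genes Apol9b (-1.68 ± 0.27), Apol9a (-1.61 ± 0.25) and Apol7a (-1.30 ± 0.25), the mitosis gene Oip5 (-1.27 ± 0.21) and the zinc finger gene Zfp473 (-1.19 ± 0.22). The largest adjusted p among these was 0.0476. Of the called genes 27.8% were higher, against 40.0% with normexp. Without the arrays that carried pancreatic transcripts 113 genes were called, in a fit on these groups alone 281, and without Card9-/- day 12 replicate 5 the count was 11.

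By list at day 12, 20 of the 45 lists were called with the preset correlation, 16 up and 4 down in the arrays labelled Card9-/-, and 0 with an estimated correlation. Among those up were complement and acute phase (0.79 ± 0.31), B cell (1.10 ± 0.63), neutrophil (0.66 ± 0.36) and extracellular matrix and fibroblast (0.54 ± 0.35), without called members (2 of complement and acute phase adjusted over the list alone). Of 36 mitosis genes 0 were called (35 lower adjusted over the list alone). The mean difference was -1.11 ± 0.31, with adjusted p = 4e-37 and adjusted p = 0.145 with an estimated correlation. Examples are the kinetochore gene Ndc80 (-1.31 ± 0.26, adjusted p = 0.0619) and the proliferation factor Foxm1 (-1.29 ± 0.30, adjusted p = 0.129). Of 34 DNA replication genes 0 were called (30 lower adjusted over the list alone). Their mean difference was -0.70 ± 0.22 and adjusted p = 0.186 with an estimated correlation. Of 34 interferon response genes 2 were lower (24 adjusted over the list alone). The mean difference was -1.09 ± 0.30 and adjusted p = 0.124 with an estimated correlation. Of 16 clock genes 4 were higher (7 higher and 2 lower adjusted over the list alone). These differed by a mean of 0.58 ± 0.16 and adjusted p = 0.124 with an estimated correlation. The exact permutation p was 0.00794 for each of these 4 lists, the smallest it can reach, and with adjustment over the 45 lists it did not pass. Within slides 1 to 4 the mitosis difference was -1.09, -1.02, -0.57 and -1.41, and the DNA replication difference -0.68, -0.52, -0.43 and -0.88. The interferon response difference was -1.43, -0.98, -0.20 and -1.49 and the circadian clock difference 0.38, 0.56, 0.50 and 0.72. Neither the IL-22 and IL-17 axis (adjusted p = 0.0745, Il22 0.27 ± 0.76 with adjusted p = 0.959), the AhR targets (adjusted p = 0.118, Cyp1a1 0.78 ± 0.51 with adjusted p = 0.735), the antimicrobial defence list (adjusted p = 0.241, Reg3g -1.97 ± 1.18 with adjusted p = 0.687) nor the tryptophan metabolism list (adjusted p = 0.356) were called, and for the last of these the mean (-0.02) and the median (0.10) differed in sign. Ido1 had a difference of -2.42 ± 0.69 with adjusted p = 0.204.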

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

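Chance flags about 1 in 20 groups under the test for an array far from the others of its group. It marked 1 of 8 array measures (12.5%), 11 of 180 list means (6.11%) and 1 of the 4 groups tested for Card9. For the other named genes it marked 175 of 2604 (6.72%), which are not listed here. The tests of the difference between genotypes over time and of pancreatic tissue were planned, as were the splits of the arrays and the fit with slide as a block. The other tests of explanations below, and the use of the slide block on the interferon list, were chosen after the result was seen.

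The Card9 probe in WT day 12 replicate 5, at -2.93, lay far from the other 4 arrays of its group, at -6.84 to -6.00. The same array had 67.9% of spots well above background, against 50.3% to 52.5%, and an eosinophil mean of 1.49, against 0 to 0.32. The pancreatic acinar mean of Card9-/- day 12 replicate 1 was 13.93, against -0.52 to 2.52, and its goblet cell mean -0.05, against -0.34 to -0.26. The proximal colon mean of WT day 12 replicate 4 was 1.46, against -0.44 to -0.10. WT day 7 replicate 3 had a wound repair mean of 1.05, against 0.36 to 0.53, and an oxidative phosphorylation mean of -0.49, against -0.06 to 0.01. The AhR target mean of WT day 7 replicate 1 was 0.89, against -0.13 to 0.08. The same array had a proximal colon mean of 2.30 and a small intestine mean of 2.20. Card9-/- day 0 replicates 1 and 2, with proximal means of 2.51 and 2.20, had AhR target means of 0.78 and 0.44. Card9-/- day 12 replicate 5 reached 0.78 with a proximal mean of -0.09. Neighbours of Card9 on chromosome 2 averaged 0.51 in WT day 7 replicate 5, against 0 to 0.10, and 0.29 in Card9-/- day 12 replicate 3, against 0.03 to 0.10. The complement and acute phase mean of Card9-/- day 7 replicate 4 was 4.07, against 3.25 to 3.32, and the crypt stem cell mean of WT day 12 replicate 2 was -0.35, against -0.08 to 0.02.

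The test of a difference between genotypes in the change over time passed for Slc16a6 (1.17, day 7 against day 0) and for Ifit1 and Oasl1 (-2.26 and -1.29, day 12 against day 7). Chance is not excluded, since 7 of 100 and 6 of 100 splits of the arrays called as many genes, and 0 genes passed with normexp, with replicate number as a block or without the pancreatic arrays.

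The Card9 probe is higher in the arrays labelled Card9-/-, where a lost transcript would make it lower. A single mislabelled array is argued against, since 0 of the 25 arrays lie on the other genotype's side. An exchange of the genotype labels as a whole stays open, since the array holds 1 probe of the gene and no other locus in the tables tells the genotypes apart. A probe outside the removed part of the gene would not by itself make the signal higher in the arrays labelled Card9-/-. The probe was well above background on 0 of 3, 1 of 5 and 1 of 5 WT arrays at days 0, 7 and 12. In the arrays labelled Card9-/- it was so on 3 of 3, 4 of 4 and 5 of 5. These values argue against the probe's place as the whole cause. Whether it plays a part stays open, as 1 probe cannot compare parts of the gene. Directions between genotypes hold only under the labels as given.

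Pancreatic acinar transcripts are high in 4 arrays, Card9-/- day 7 replicates 2 and 3, Card9-/- day 12 replicate 1 and WT day 12 replicate 5. A level set by genotype and day is argued against by a range of 15.42 within a group. The size of that range is uncertain, since most acinar genes were not well above background at day 0. The rank test of low signal, chosen after the result was seen, did not decide. Of the 4 arrays 3, all but WT day 12 replicate 5, are among the 4 lowest signals. WT day 7 replicate 5, the other of those, has an acinar mean of 2.28. Low signal as the whole cause is argued against by the sizes. The 75th percentiles of signal lay between 196.1 and 661.3 on a linear scale, far too narrow a range for log2 means of 8.51 to 14.78. WT day 12 replicate 5 had a signal of 465.4. Pancreatic tissue in the sample may be the source, as the mean over 7 other pancreatic genes was above each of the 21 remaining arrays in all 4 (lowest 0.92, against at most 0.80). In WT day 12 replicate 5 that 0.92 rests on Ptf1a (4.10, the other 6 genes at -0.90 to 0.97), which was as high in WT day 7 replicates 4 and 5 (4.87 and 4.32), so the source in this array stays open, and no biological explanation was tested.

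The interferon response list was lower in the arrays labelled Card9-/- at day 12 with the preset correlation, with 2 of 34 genes called, adjusted p = 0.124 with an estimated correlation and an exact permutation p adjusted over the lists of 0.0715. Slide as the whole cause is argued against by a shift of -1.10 ± 0.32 with slide as a block. The arrays with pancreatic transcripts as the whole cause are argued against by a shift of -1.20 without them (exact permutation p = 0.0286, 70 splits, 4 arrays against 4). Another time of day at sampling stays open, since the clock genes differed by 2.24 between a first set of 9 (mean 1.48) and a second set of 4 (mean -0.75), and the hour of sampling is not in the labels, though the sets were also opposed at day 0 (0.97 and -0.60) and day 7 (0.66 and -0.33), where the interferon response list was not lower (0.16 ± 0.39 and 0.43 ± 0.32). Genotype, as labelled, may be the cause and was not tested apart from that hour (2.24). The unknown hour limits the mitosis and DNA replication differences at day 12 in the same way. It also limits day 12 against day 7 in WT, where clock genes moved too.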

How the results depend on the processing

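Counts of called genes were recomputed under each alternative. For results that moved or reversed, the cause was not tested unless stated. Omitting the pancreatic arrays, omitting the 2 arrays with the most spots above background, the proximal colon covariate and the list count without each array were chosen after seeing the data. Counts not given here stayed within 1.5 times. A list is called reversed where the direction of its test changed.

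With normexp the counts were 41 for genotype at day 7, 10 for genotype at day 12, 290 for day 12 against day 0 in WT and 0 for the difference between genotypes in the change to day 7 and 0 in the change from day 7 to day 12. Dclk1 at day 7 in Card9-/- reversed to 0.55, and to 0.49 in the series value table, where genotype at day 7 gave 269. With quantile normalization genotype at day 0 gave 3, day 12 against day 7 in WT 59 and the later difference in change 0. No filter on dim probes gave 6 for genotype at day 7, 47 and 1278 for day 12 against day 7 in WT and Card9-/-, and 0 for the earlier difference in change. A filter of 13 arrays gave 369, 220 and 11 for genotype at day 7, day 12 against day 7 in WT and the later difference in change. Every probe on its own gave 2 for genotype at day 0 and 0 for the earlier difference in change. With slide as a block genotype at day 0 called 1 gene, lower and not Card9 (4.64, adjusted p = 0.131), genotype at day 7 gave 357 and day 12 against day 0 in Card9-/- 1121.

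Replicate numbers were not taken as pairs. Same-number arrays had a mean residual correlation of 0.025 against -0.00173 for others, with 15 of 54 pairs over 0.1, and no comparison had every pair over 0.1. For day 12 against day 7 in WT all 5 pairs were positive (0.0515 to 0.68, 3 over 0.1). With replicate number as a block genotype at day 7 gave 30, day 12 against day 7 in WT 81, day 12 against day 0 in WT 291 and both differences in change 0.

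Fitted on its own groups, each contrast took its spread from fewer arrays and from those groups alone. Genotype then gave 0, 1 and 281 at days 0, 7 and 12, and day 7 against day 0 gave 38 and 2396 in WT and Card9-/-. Day 12 against day 7 gave 0 and 683, both differences in change 0, and 383 of the named gene results passed instead of 592. Fewer arrays alone do not account for a count that rose, as for genotype at day 12 from 18 to 281. Whether the spread differs between the groups was not tested. Of the list results, 258 of 495 passed, 23 with an estimated correlation and 118 with fry. The exact permutation test, adjusted over the lists, passed for 19 and 18 lists for day 12 against day 0 in WT and Card9-/-. In each other contrast it passed for 0 lists.

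Without the pancreatic arrays genotype gave 2, 1 and 113 at days 0, 7 and 12, Card9-/- day 7 against day 0 gave 3274, day 12 against day 7 gave 28 and 247 in WT and Card9-/-, day 12 against day 0 in WT 246 and both differences in change 0. The mitosis list reversed to 0 for genotype at day 7 and 0.18 for the earlier difference in change, and the acinar list to -0.71 for genotype at day 7, 0.77 for day 12 against day 7 in Card9-/-, and -0.53 and 0.32 for the differences in change. Without the 2 arrays with the most spots above background genotype gave 3 and 7 at days 0 and 7, day 12 against day 7 in WT 49, the earlier difference in change 0, and smooth muscle at day 7 in WT reversed to 0.26.

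With the proximal colon covariate genotype at day 0 gave 2, day 7 against day 0 in Card9-/- 3263, day 12 against day 7 in WT 281, day 12 against day 0 gave 704 and 239 in WT and Card9-/-, and the differences in change 0 and 4. Smooth muscle reversed to -0.39, -0.14, 0.22 and 0.13 and adipocyte to -1.19, 1.38 and 0.65 for genotype at day 0, Card9-/- day 7 and day 12 against day 0, and, for smooth muscle, the earlier difference in change. Interferon reversed to -0.32 in the earlier difference in change. The proximal list went to 0 for genotype at day 0, day 12 against day 0 in Card9-/- and the earlier difference in change, since the covariate is its own mean.

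Leaving out 1 array gave 0 to 58, 4 to 2266 and 11 to 22 for genotype at days 0, 7 and 12, 393 to 1590 and 3224 to 5484 for day 7 against day 0 in WT and Card9-/-, 28 to 227 and 1033 to 2260 for day 12 against day 7, 112 to 365 and 479 to 1963 for day 12 against day 0, and 0 to 528 and 0 to 62 for the differences in change. The lists that passed numbered 249 to 265 and the named gene results 478 to 745. Where 1 array left out reversed a list, its mean over these fits ranged from -0.58 to 0.05 for extracellular matrix at day 0 (highest without WT day 0 replicate 3) and from -0.41 to 0.26 for smooth muscle at day 7 in WT (highest without WT day 7 replicate 5). DNA replication at day 7 ranged from -0.19 to 0.39 (lowest without Card9-/- day 7 replicate 1), and interferon for day 12 against day 7 in WT was -0.28 without WT day 7 replicate 1. Mitosis ranged from -0.83 to 0.02 for genotype at day 7 and from -0.66 to 0.20 for the earlier difference in change (each highest without Card9-/- day 7 replicate 3), and from -0.77 to 0.08 for day 12 against day 7 in Card9-/- (highest without Card9-/- day 7 replicate 1).

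Of the results for named genes, 2289 kept their direction and their side of the threshold with normexp, 2348 with quantile normalization and 2361 with no filter on dim probes. With slide as a block 2313 did so, with replicate number as a block 2343 and when fitted on their own groups 2142. In the main fit 592 were called, so most of those kept were results that stayed uncalled. On their own groups 252 called results were no longer called. Signal over background limits the folds of genes dim in a group, which are given as bounds, and between 48.0% and 67.9% of spots were well above background.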

Other observations

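Mast cell proteases rose over the time course in both genotypes. Mcpt4 was up by 1.90 ± 0.35 at day 7 and 3.56 ± 0.35 at day 12 in WT, and by 4.68 ± 0.35 at day 12 in the arrays labelled Card9-/-. The mast cell list rose by a mean of 1.57 ± 0.25 and 2.19 ± 0.25 in WT and by 2.50 ± 0.26 and 3.03 ± 0.25 in the arrays labelled Card9-/-. At day 12 the genotypes differed on the mast cell list by 0.71 ± 0.22 (adjusted p = 0.000572 and adjusted p = 0.124 with an estimated correlation), and Mcpt4 itself was not called between them (adjusted p = 0.475).

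The splits of the arrays into groups of the same sizes were planned. For day 7 against day 0, the real split called the most genes, which makes chance unlikely. As large were 1 of 56 splits in WT (1102, highest other 685) and 1 of 35 in the arrays labelled Card9-/- (4998, highest other 3386). The same holds for day 12 against day 7, with 1 of 100 splits as large in WT (124, highest other 16) and 1 of 100 in Card9-/- (1960, highest other 868), and for day 12 against day 0, with 1 of 56 in each genotype (441 and 1769, highest others 4 and 77). For genotype at day 12 chance is also unlikely, with 1 of 100 splits as large (18, highest other 1). These shares were not adjusted over the contrasts. For genotype at day 7 chance cannot be excluded, with 11 of 100 splits as large (140, highest other 3083), and splits that call so many genes point to a structure of the arrays other than genotype. For the difference between genotypes in the change over time chance cannot be excluded either, with 7 of 100 splits as large to day 7 (1, highest other 368) and 6 of 100 from day 7 to day 12 (2, highest other 972). At day 0, 2 of the 10 splits called as many genes (1, highest other 4), and 10 splits are too few for a share under 0.05. Between 2 groups, no drawn split that left the sides without a common slide gave a result as large. How many such splits were drawn was not recorded, so this does not test the slides. For the differences in change the slides were not looked at.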
